A study of Mus musculus with 6 samples.

How the data were processed

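RNA was measured in effector memory CD4+ T cells, antigen-experienced helper T cells, sorted alive from mouse spleens. The labels give 3 libraries from Il1rn knockout mice (Il1rnKO 1 to 3) and 3 from wild-type mice (WT 1 to 3). Il1rn encodes the interleukin-1 receptor antagonist, a secreted protein that keeps interleukin-1 from signalling through its receptor. Libraries were made from poly(A)-selected RNA with a kit that keeps strand information and were read from both ends, 150 bases each, per the labels' protocols. The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

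The deposited table holds estimated counts per gene, many of them with decimals, for 34866 genes with versioned Ensembl identifiers and no scaling to a common total. The genome build was GRCm38, per the submitters' processing notes. The aligner, the program that estimated the counts and its use of strand are not given in the sources used here. Reads shared by near-identical genes may therefore have been divided between them by an estimate, and genes that overlap on opposite strands may share reads. No column was left unassigned to a sample.

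Estimated counts were rounded to whole numbers. Gene symbols and coordinates came from GENCODE M21, an annotation of the same build; 34582 identifiers matched with the version left off, 284 did not, and 32574 matched with their version. Library totals lay between 14102183 and 17677217 counts, so that 1 CPM (the usual unit of counts scaled to the library total) stood for 14.1 to 17.7 counts.

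Knockout and wild type were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with the group (a minimum count of 10 and a minimum total of 15), and the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 13374 genes, and the common biological coefficient of variation was 0.286. Log2 fold changes are knockout over wild type, with their standard error (SE). CPM values are TMM-scaled except for Il1rn, the neutrophil list and the sums of lists, which use plain library totals. For a gene with 0 counts in every library of a group, the fold is a lower bound set by 3 counts over that group's libraries together, which covers counting error only.

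Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, adjusted over the 31 lists with at least 5 tested members. Of 38 lists fixed beforehand, 21 were T cell and metabolic programmes and 17 were markers of other cell types, RNA quality and sex. Beside it stand camera with a correlation estimated per list and fry, which asks whether a list's genes moved on balance one way or, in its mixed form, in either direction, without comparing them with other genes.

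The comparison, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Il1rn first. It then took up to 10 genes per direction that passed the threshold with CPM ranges that did not overlap and a mean log2 CPM of at least 1, leaving out unnamed gene models, pseudogenes and antigen receptor segments; with fewer than 5 in a direction it took the 5 with the smallest p. In each list it took up to 4 members past the threshold or, with none, the 2 with the smallest p. It added 17 helper T cell genes whatever their result. Some genes that the rule named are not reported here.

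The fits were tested on counts simulated from the means and dispersions of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. Each gene was drawn independently, without variation shared between genes, so recovery in the real libraries may be lower. Further genes, shifted less for a check of the list tests, were counted neither as recovered nor as false calls. For Il1rn knockout against wild type, edgeR recovered 45% of the 2-fold and 79% of the 4-fold genes with 8 false calls among 12860 genes. DESeq2 1.42.0 recovered 57% and 80% with 30 false calls among 13374 genes. On the real libraries DESeq2 was run without the filter, on 20255 genes, so this simulation does not describe that fit. Limma voom with quality weights recovered 41% and 78% with 11 false calls among 12860 genes. Alternatives were RLE and upper-quartile normalization, no filter and a stricter filter (50 counts in 3 libraries), the replicate number as a block, each library left out, DESeq2, limma voom with quality weights, a robust edgeR fit, and leaving out receptor segments or mitochondrial and sex-linked genes. Camera without the neutrophil list, the mitochondrial share as a covariate and a term for the side of a split of the libraries were added after the data had been seen. The list of X-inactivation genes was not analysed here.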

Results

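Gene expression was measured in splenic CD4+ T cells of the effector memory type, sorted from Il1rn knockout and wild-type mice, with 3 libraries in each group. Total counts were 17677217, 16883997 and 14102183 in WT 1, 2 and 3, and 17006198, 14158897 and 17205393 in Il1rnKO 1, 2 and 3. Between 15665 and 17057 genes had at least 1 count in a library. The comparison asks which transcripts of these T cells differ when the antagonist of interleukin-1 is missing.

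Il1rn itself was barely detected in either group. The gene lies on chromosome 2 from 24336853 to 24351494 (GRCm38; ENSMUSG00000026981.15). Its rounded counts were 6, 10 and 0 in WT 1, 2 and 3 and 1, 3 and 1 in Il1rnKO 1, 2 and 3. The means were 0.311 ± 0.297 CPM in wild type and 0.11 ± 0.0886 CPM in knockout (SD, n = 3), with overlapping ranges. These counts were below the filter and too few to check the genotype labels, and what part of the gene the allele removes was not analysed here.

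Knockout and wild-type cells differed in 7 of 13374 tested genes, 4 higher and 3 lower in the knockout, and no helper T cell cytokine or lineage regulator was among them. Sfmbt2, a Polycomb-group gene that carries a large microRNA cluster in an intron, fell from 59.5 ± 4.90 to 8.74 ± 0.645 CPM (SD, n = 3). Ngp, which encodes a granule protein of neutrophils, had 0 counts in every wild-type library and 104 to 247 counts in the knockout libraries, at least 158-fold higher. H2-Q7 and H2-Q6, nonclassical major histocompatibility complex class I genes, rose from 295 ± 15.3 to 768 ± 104 CPM and from 168 ± 18.3 to 386 ± 36.5 CPM (SD, n = 3). Arl2bp, which encodes a binding partner of the small GTPase ARL2, rose from 26.9 ± 0.230 to 87.1 ± 17.7 CPM (SD, n = 3).

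By edgeR's quasi-likelihood test, Sfmbt2 (ENSMUSG00000061186.15, chromosome 2, 10370510 to 10595253) had a log2 fold change of -2.77 (SE 0.17, adjusted p = 9.82e-05). Arl2bp (ENSMUSG00000031776.17, chromosome 8, 94666600 to 94674425) had a log2 fold change of 1.70 (SE 0.18, adjusted p = 0.00765 by edgeR). Ngp (ENSMUSG00000032484.8, chromosome 9, 110419747 to 110423012) had an adjusted p of 0.00765 by the same edgeR test. H2-Q7 (ENSMUSG00000060550.15, chromosome 17, 35439155 to 35443773) and H2-Q6 (ENSMUSG00000073409.12, chromosome 17, 35424850 to 35430055) had log2 fold changes of 1.38 (SE 0.17) and 1.20 (SE 0.16), with edgeR adjusted p of 0.0213 and 0.0293. These neighbours are near-identical copies among which reads may have been divided, so their single values are uncertain; the CPM summed over 8 H2-Q genes was 1480 ± 58.3 in wild type and 2360 ± 259 in knockout (SD, n = 3). Another, Gm13443 (ENSMUSG00000075391.6, chromosome 2, 35340409 to 35340963), is annotated as a processed pseudogene and was singled out after its values were seen. It had 221 to 383 counts in the wild-type libraries and 0 in every knockout library, at least 324-fold lower (edgeR adjusted p = 0.000188), and its reads may belong to a near-identical gene.

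The remaining 4 genes named by rank did not pass the edgeR test with the main settings, though Glo1 and Srp54b passed in 7 of 19 gene-level fits, Dnah8 in 6 and Ltf in 4. For each gene these include the mitochondrial share and the side of the library split as terms, added after the data were seen. Otherwise Ltf passed with no filter and with DESeq2 alone. Ltf, the lactotransferrin gene, had a log2 fold change of 6.86 (SE 1.08, adjusted p = 0.112 by edgeR). With a library left out it ran from 5.594 to 10.373, highest without WT 1. There the remaining wild-type libraries had 0 counts, so 10.373 is a fitted value and not a measured fold. Glo1, which encodes a methylglyoxal-detoxifying enzyme, and Dnah8, an axonemal dynein gene that overlaps it on the opposite strand, had log2 fold changes of -1.38 (SE 0.24) and -1.30 (SE 0.24). Srp54b, a copy of the signal recognition particle gene Srp54 with close paralogs, had -1.99 (SE 0.38). The edgeR adjusted p of these 3 genes were 0.210, 0.305 and 0.344; with DESeq2 they were 1.4e-05, 2.05e-05 and 2.05e-05 (0.0075 for Ltf), and without Il1rnKO 3 Glo1 (0.0129) and Srp54b (0.0105) passed edgeR. At an unadjusted p under 0.05 there were 545 genes, 339 higher and 206 lower, against 669 that chance alone would give. Sfmbt2, Ngp and Gm13443 passed in all 19 gene-level fits. Without WT 1, WT 2, WT 3, Il1rnKO 1 or Il1rnKO 2, 3, 4, 3, 4 and 4 genes passed; the highest adjusted p with a library left out was 0.0967 for Arl2bp, 0.321 for H2-Q7 and 0.406 for H2-Q6.

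**Figure D1:**
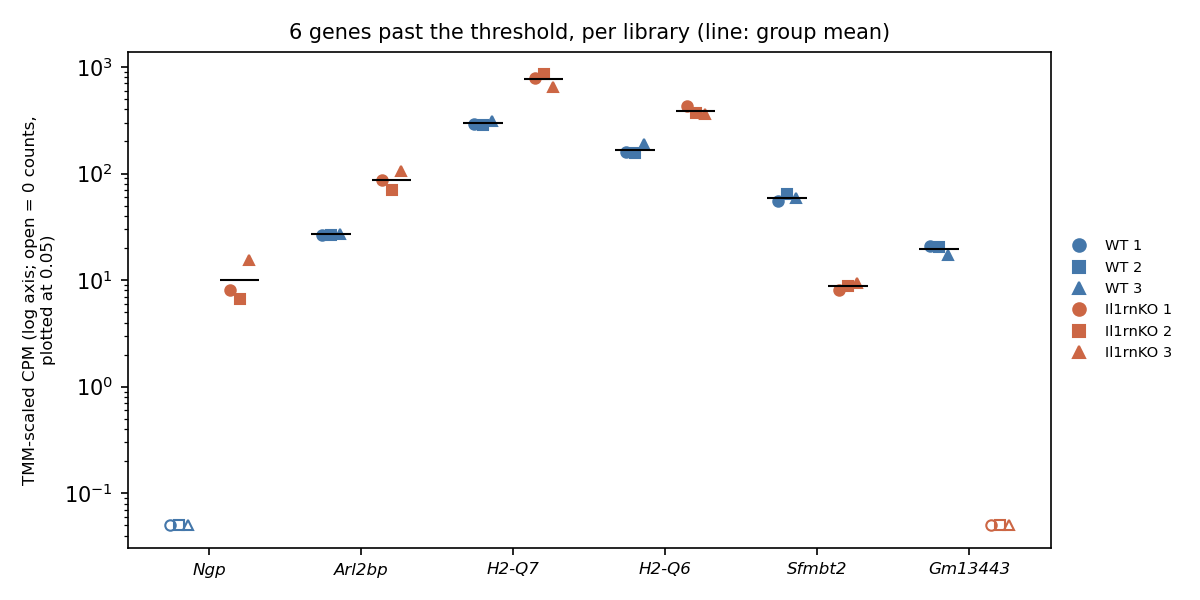
TMM-scaled CPM (log axis) of 6 of the 7 genes that passed the threshold, with a point per library and a line at each group mean; open points are libraries with 0 counts, drawn at a CPM of 0.05. Wild-type and knockout libraries do not overlap for any of these 6 genes, and Ngp and Gm13443 had 0 counts throughout one group.

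Genotype did not set the main axis of variation among the libraries. The first principal component held 30.2% of the variance, with scores of 8.48, -16.81 and -51.83 in WT 1, 2 and 3 and 30, 51.11 and -20.93 in Il1rnKO 1, 2 and 3. Spearman correlations across genes were 0.976 to 0.981 within wild type, 0.968 to 0.983 within knockout and 0.966 to 0.986 between groups. A split of WT 1, Il1rnKO 1 and Il1rnKO 2 from WT 2, WT 3 and Il1rnKO 3 called 887 genes by edgeR, none of them among the 7 genotype calls. Within the first of these sides, the log2 difference of mean CPM (0.1 CPM added) between knockout and wild type was -2.70 for Sfmbt2, 1.54 for Arl2bp, 1.51 for H2-Q7 and 1.32 for H2-Q6. Within the other side it was -2.71, 1.96, 1.14 and 1.07 for Sfmbt2, Arl2bp, H2-Q7 and H2-Q6. The ranges of these genes did not overlap between the groups, so the sign within each side was fixed in advance. Such genes were also unlikely to be called by a split that crosses the groups, so neither result is a check on it. WT 1 was the only wild-type library of the first side, and Il1rnKO 3 the only knockout library of the other. With the side as a term, edgeR called 12 genes, including all 7; this split was found in the same data, so the fit was chosen after they were seen.

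Transcripts of neutrophils were higher in the knockout libraries. Of the 10 tested members of the neutrophil list, 9 had positive fold changes, with a median log2 fold change of 4.06, which was 4.06 also with Ngp at its lower bound. Ngp alone passed over all genes tested (with no filter S100a9, S100a8 and Ltf passed too), and 6 members (Ngp, Ltf, S100a9, S100a8, Lcn2 and Camp) passed when adjusted over the list alone. S100a9 and S100a8, which encode the subunits of calprotectin, had log2 fold changes of 4.96 (SE 0.98) and 4.27 (SE 0.86), and their highest level was 34.2 and 18.8 CPM, in Il1rnKO 3. With a library left out these ran from 3.999 to 8.729 for S100a9 and from 3.437 to 5.083 for S100a8, lowest without Il1rnKO 3 and highest without WT 1. By contrast, Cxcr2 and Csf3r, receptors of mature neutrophils, had log2 fold changes of 0.60 (SE 0.48) and 1.86 (SE 0.94; -0.051 without Il1rnKO 3), and Il1r2, the interleukin-1 decoy receptor, had -0.32 (SE 0.49). The list's camera adjusted p was 1.7e-10 with the preset correlation; the adjusted p = 0.35 with an estimated correlation, and 0.0405 with fry.

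**Figure D2:**
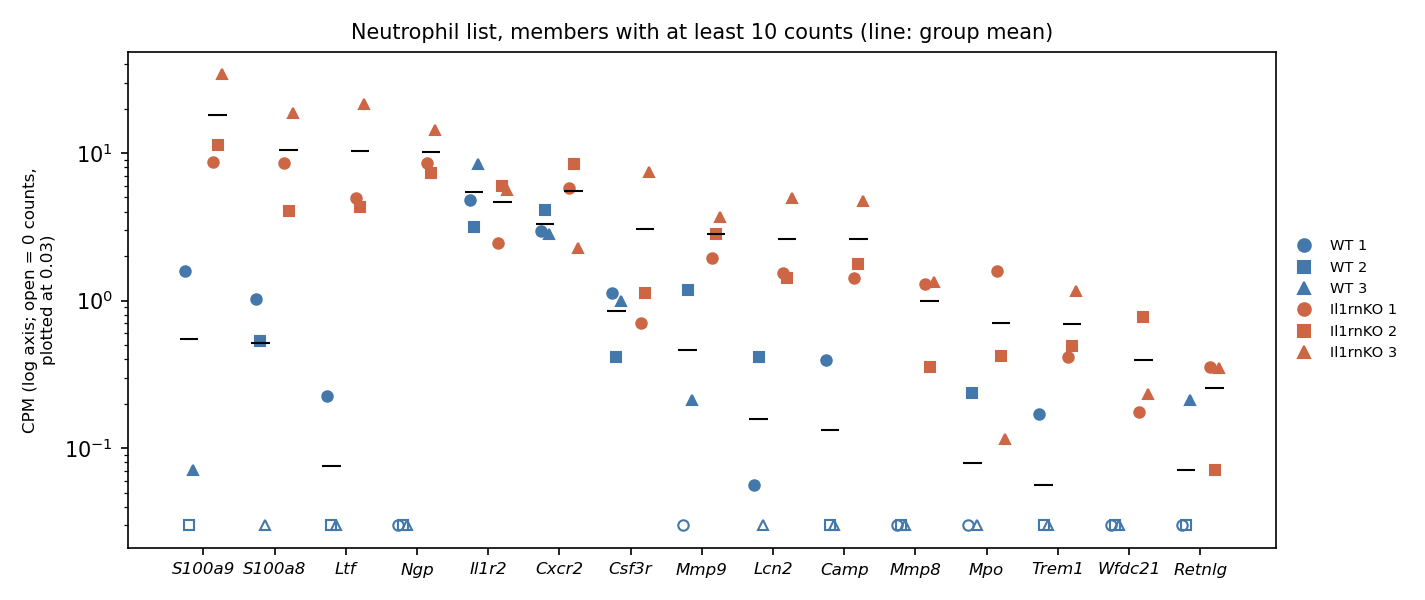
CPM (log axis) of the 15 members of the neutrophil list with at least 10 counts over all libraries, with a point per library and a line at each group mean; open points are libraries with 0 counts, drawn at 0.03. For 10 of the 15 members every knockout library lay above every wild-type library.

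Genes of regulatory T cells were higher and genes of naive and central memory T cells were lower in the knockout, each as a list and by small amounts. In the regulatory T cell list 15 of 17 members had positive fold changes (median 0.254 on the log2 scale), and in the naive and central memory list 14 of 17 had negative ones (median -0.195). Foxp3, the regulator that defines regulatory T cells, was at 94.3 ± 25.4 CPM in wild type and 151 ± 30.8 CPM in knockout (SD, n = 3), a log2 fold change of 0.68 (SE 0.22), and Itgae, the integrin CD103, had 0.69 (SE 0.18). Ccr7, a chemokine receptor for entry into lymph nodes, had a log2 fold change of -0.68 (SE 0.24). None of the members of either list passed over all genes tested or when adjusted over the list alone. The camera adjusted p was 0.00528 for both lists; with an estimated correlation the adjusted p = 0.35 and 0.841, and with fry 0.0994 and 0.773. The regulatory T cell call was lost without WT 2 (adjusted p = 0.0533 by camera) or Il1rnKO 3 (0.0537), and the naive and central memory call without WT 2 (0.171), Il1rnKO 2 (0.0672) or Il1rnKO 3 (0.0721), while its median was -0.30 without WT 3.

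Helper T cell programmes did not pass as lists in the comparison of all 6 libraries. Of the signature cytokines, Ifng was at 172 ± 15.8 CPM in wild type and 142 ± 60.5 CPM in knockout, Il4 at 5.61 ± 1.52 and 5.95 ± 1.04 CPM, Il17f at 1.66 ± 0.808 and 0.861 ± 0.729 CPM, and Il17a at 0.616 ± 0.212 and 0.597 ± 0.463 CPM (SD, n = 3); Csf2 was below the filter. Log2 fold changes of the lineage regulators were 0.33 (SE 0.25) for Tbx21 of Th1 cells, 0.25 (SE 0.19) for Gata3 of Th2 cells and 0.01 (SE 0.25) for Bcl6 of follicular helper cells, the last of which was -0.002 with RLE size factors. Median log2 fold changes were 0.24 for the Th1 and cytotoxic list (13 of 19 positive), 0.10 for Th2 (7 of 11), 0.14 for Th17 (9 of 16) and -0.11 for follicular helper cells (6 of 18). With a library left out the Th1 median was lowest without Il1rnKO 2 (0.051), the Th2 median ran from -0.063 without WT 1 to 0.179 without WT 2, and the Th17 median from -0.273 without Il1rnKO 3 to 0.288 without WT 3. Camera adjusted p for these 4 lists were 0.378, 0.429, 0.707 and 0.379; the follicular helper list passed downward without WT 2 (median -0.186, adjusted p = 0.0328). Among other members, Il18rap had 0.67 (SE 0.18), Gzmk -0.68 (SE 0.29), Il17rb 0.40 (SE 0.23), Ltb4r1 1.06 (SE 0.70), Cxcr5 -0.64 (SE 0.27) and Ascl2 1.81 (SE 1.03). The receptors Cxcr3 and Ccr6 had 0.36 (SE 0.23) and 0.27 (SE 0.27), and the proliferation marker Mki67 had 0.19 (SE 0.21).

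The list of interleukin-1 family ligands and receptors did not pass camera, with members on both sides of 0. Il1rl1, the receptor for interleukin-33, was at 19.1 ± 1.55 CPM in wild type and 44.1 ± 13.4 CPM in knockout (SD, n = 3). Its log2 fold change was 1.21 (SE 0.22), and it did not pass over all genes with the main settings (edgeR adjusted p = 0.272). It passed in 4 of 19 fits: with no filter, with DESeq2 (0.00306), and with the mitochondrial share or the side of the library split as a term. Those terms were added after the data were seen, and no alternative fixed beforehand called it with the main filter. Il1rl1 and Il18rap, a subunit of the interleukin-18 receptor, passed when adjusted over the list alone (0.00269 and 0.024), as Il1rl1 did in the Th2 list (0.00246). Il1r1, Il1r2 and Il1rap, which bind interleukin-1, had log2 fold changes of -0.47 (SE 0.49), -0.32 (SE 0.49) and -0.33 (SE 0.22). Of 12 tested members 6 were positive and 6 negative (median 0.10, camera adjusted p = 0.439), and the list passed in fry's mixed form alone (adjusted p = 0.00277), as the neutrophil list also did.

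Inflammatory response programmes did not pass either with all 6 libraries and the main settings. In the interferon response list 29 of 38 members had positive fold changes (median 0.15, camera adjusted p = 0.0563, and 0.841 with an estimated correlation), among them Ifi44 with 1.19 (SE 0.35) and Xaf1 with 0.42 (SE 0.17). This list passed camera with upper-quartile normalization (0.0493), a stricter filter (0.0101), the mitochondrial share as a covariate (0.000142) and the side of the library split as a term (0.00285), and without WT 3 (0.00801) or Il1rnKO 2 (0.00153). Its median was 0.055 without Il1rnKO 3 (0.642), 0.08 without WT 1 (0.242) and 0.08 without WT 2 (0.485). The targets of interleukin-1 and NF-kappaB had a median of -0.02 (12 of 25 positive, adjusted p = 0.837; mean 0.03, with the test upward), with Bcl3 at 0.40 (SE 0.25) and Icam1 at 0.28 (SE 0.19). The interleukin-6 and STAT3 list had a median of 0.09 (8 of 15 positive, mean -0.09, adjusted p = 0.716), with Socs3 at 0.44 (SE 0.18) and Cish at 0.46 (SE 0.20). The list of pathogenic helper cytokines had a median of -0.05 (5 of 14 positive, adjusted p = 0.586), with Il2 at -0.67 (SE 0.36). The immediate early list had a median of -0.01 (12 of 27 positive, adjusted p = 0.492; -0.076 and 0.0444 without WT 3), with Nr4a3 at -1.62 (SE 0.43; -0.785 without WT 2, and past the threshold with no filter alone) and Fosb at 0.52 (SE 0.21), and the inhibitory receptor list had 0.04 (9 of 16 positive, mean -0.08, adjusted p = 0.866), with Entpd1 at 0.38 (SE 0.22).

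Homing, residency and growth lists did not pass with the main settings. The chemokine receptor list had a median log2 fold change of 0.27 (16 of 25 positive, camera adjusted p = 0.281), and passed with the side of the library split as a term (0.148, 0.0332). The tissue residency list had 0.17 (10 of 14 positive, adjusted p = 0.582); Itgae passed when adjusted over that list alone (0.0473), and Rgs2 had -0.86 (SE 0.27), which passed over all genes with no filter alone (0.025). The cell cycle list had 0.12 (26 of 39 positive, adjusted p = 0.492), with Tk1 at 0.72 (SE 0.31) and Kif11 at -0.72 (SE 0.42).

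Ribosomal protein and mitochondrially encoded transcripts were lower in the knockout as lists, and their shares also varied widely within each group. All 38 ribosomal protein genes had negative fold changes (median -0.28) and all 13 mitochondrially encoded genes did (median -0.575), with none passing singly; Rpl5 and Rpl3 had -0.40 and -0.37 (SE 0.24 each), and mt-Nd3 and mt-Atp8 had -0.68 (SE 0.35) and -0.63 (SE 0.37). Mitochondrially encoded transcripts took 5.676, 7.317 and 8.917% of the counts in WT 1, 2 and 3 and 3.686, 3.438 and 8.339% in Il1rnKO 1, 2 and 3. Ribosomal protein transcripts took 2.675, 3.019 and 3.745% in WT 1, 2 and 3 and 2.262, 2.102 and 3.828% in Il1rnKO 1, 2 and 3. The camera adjusted p were 2.64e-05 and 1.94e-05 with the preset correlation of 0.01. The estimated correlations between members were 0.829 and 0.986, so the members of each list are far from independent. With these the camera adjusted p = 0.841 for both lists, and with fry 0.846 and 0.773. The ribosomal call was lost without Il1rnKO 2 (median -0.10, adjusted p = 0.186), with the side of the library split as a term (-0.10, 0.107), and turned upward with the mitochondrial share as a covariate (0.12, 0.00746). Its median was -0.45, -0.09, -0.14 and -0.68 without WT 1, WT 3, Il1rnKO 1 and Il1rnKO 3, and that of the mitochondrial list -0.36, -0.38, -0.34 and -1.20 without WT 3, Il1rnKO 1, Il1rnKO 2 and Il1rnKO 3.

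**Figure D3:**
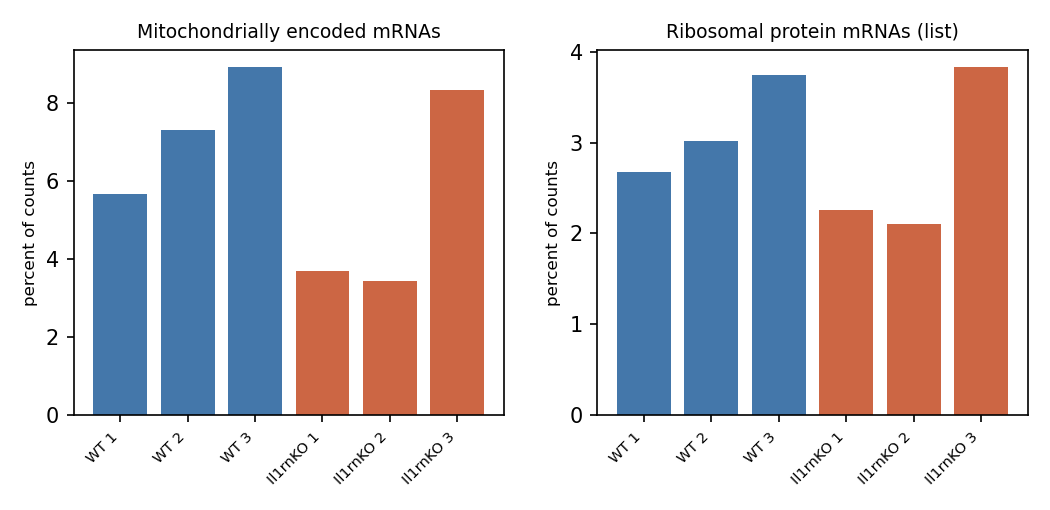
Percent of each library's counts in mitochondrially encoded transcripts (left) and in the ribosomal protein list (right), a bar per library, wild type in blue and knockout in orange. Il1rnKO 3, at 8.339% and 3.828%, lies among or above the wild-type libraries, and Il1rnKO 1 and Il1rnKO 2 lie below them.

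Metabolic and stress lists did not pass with the main settings. Nuclear genes of oxidative phosphorylation had a median log2 fold change of -0.08 (25 of 35 negative, camera adjusted p = 0.233), with Ndufa8 at 0.71 (SE 0.25) and Cox6a1 at 0.30 (SE 0.23). This list passed in opposite directions in other fits: upward with the mitochondrial share as a covariate (0.17, adjusted p = 0.00183) and downward without Il1rnKO 3 (-0.292, 7.31e-06). Glycolysis and hypoxia genes had a median of 0 (12 of 24 positive, adjusted p = 0.749, with the test downward), with Egln3 at -0.70 (SE 0.22) and Ero1l at 0.29 (SE 0.14). Cholesterol synthesis genes had -0.13 (14 of 22 negative, adjusted p = 0.378), with Mvd at 0.53 (SE 0.22) and Lss at 0.54 (SE 0.26). Unfolded protein response genes had -0.05 (13 of 17 negative, adjusted p = 0.234), with Dnajb9 at -0.47 (SE 0.18) and Atf4 at -0.26 (SE 0.17), and dissociation and heat shock genes had -0.04 (10 of 17 negative, adjusted p = 0.429), with Hsp90aa1 at -0.42 (SE 0.25) and Dnaja1 at -0.29 (SE 0.19).

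Apart from the neutrophil list, markers of other cells that a spleen sort could hold did not pass camera with the main settings, though some of their sums did not overlap between the groups. Lyz2, a lysozyme gene of macrophages and neutrophils, was at 3.01 ± 4.15 CPM in wild type and 12.0 ± 6.33 CPM in knockout (SD, n = 3), a log2 fold change that passed with no filter alone (1.958, 0.0256) and was 4.24 without WT 1, and Ccr2 had a log2 fold change of 0.67 (SE 0.35); the macrophage and monocyte list had a median of 0.32 (8 of 12 positive, camera adjusted p = 0.306). That list passed upward with no filter (median 1.35, adjusted p = 0.00494) and without WT 1 (0.594, 0.001), WT 3 (0.536, 0.0333) or Il1rnKO 1 (0.223, 0.0293). Dendritic cell genes had 0.325 (7 of 9 positive, adjusted p = 0.378), with Ccr9 at 0.73 (SE 0.41) and Zbtb46 at 0.74 (SE 0.66). B cell genes had 0.26 (7 of 10 positive, adjusted p = 0.378; 0.002 without Il1rnKO 3 and 0.547 without WT 1), with Cd22 at 0.73 (SE 0.27) and Ighm at 0.32 (SE 0.14). Plasma cell genes had 0.16 (3 of 6 positive, adjusted p = 0.606, with the test downward), with Irf4 at -0.52 (SE 0.20) and Igkc at 0.88 (SE 0.75), and erythroid genes had 0.01 (3 of 6 positive, adjusted p = 0.866), with Hbb-bs at 1.86 (SE 0.73) and Tfrc at -0.47 (SE 0.21). Pan T cell genes had -0.08 (8 of 14 negative, adjusted p = 0.586), with Cd3e at 0.29 (SE 0.17) and Cd247 at -0.33 (SE 0.21). Genes of gamma-delta T and natural killer T cells had 0.15 (5 of 8 positive, adjusted p = 0.655), with Zbtb16 at 0.37 (SE 0.22) and Tcrg-C2 at 0.28 (SE 0.34).

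Lists with under 5 tested members were summed per library. Cd8a and Cd8b1 together reached 3.62 to 5.04 CPM in wild type and 5.23 to 7.15 CPM in knockout, with no overlap. Natural killer cell markers summed to 15.9 to 21.4 and 11.8 to 23.2 CPM in wild type and knockout, and mast cell, basophil and eosinophil markers to 13.6 to 18.7 and 14.1 to 22.3 CPM. Platelet markers summed to 45.7 to 63.9 CPM in wild type and 71.8 to 87.9 CPM in knockout, with no overlap, and stromal and endothelial markers to 98.3 to 118 and 109 to 140 CPM. Y-linked genes summed to 10.2 to 13.9 CPM in wild type and 10.9 to 15.7 CPM in knockout. Among lists with more members, the sums of B cell genes (121 to 165.8 CPM in wild type, 170.9 to 210.2 in knockout) and dendritic cell genes (62.49 to 76.14 and 86.38 to 96.26 CPM) did not overlap either, nor did those of neutrophil genes (10.01 to 12.76 and 48.57 to 120.7 CPM). Of 12 lists for other cells, 5 had sums higher in every knockout library and 0 lower. This was not particular to markers of other cells. Sums of Th1 genes (880.8 to 912.2 CPM in wild type, 1011 to 1145 in knockout) were also apart. So were those of regulatory T cell genes (1088 to 1302 and 1407 to 1780 CPM), while most other programmes overlapped. TMM factors ran from 0.917 in WT 3 to 1.104 in Il1rnKO 2, so narrow gaps, as for CD8 genes, may depend on the scaling. Tests of the log2 sums, chosen after the sums were seen, were adjusted over the 12 lists for other cells and the Y-linked one. By limma, which pooled the variance over the 13 sums, the neutrophil sum alone passed (log2 ratio 2.52, SE 0.23, adjusted p = 2.73e-14). That call rests on the pooling: with each sum's own variance on 4 residual degrees of freedom, 0 of 13 passed, and the neutrophil sum had an SE of 0.44 and an adjusted p of 0.0606. Adjusted p by limma were 0.127 for CD8 (log2 ratio 0.54), 0.133 for platelet (0.50), 0.171 for B cell (0.45) and 0.197 for dendritic cell genes (0.41), and with their own variances 0.15, 0.15, 0.15 and 0.105. Chance alone separates 3 libraries from 3 in 10% of lists.

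**Figure D4:**
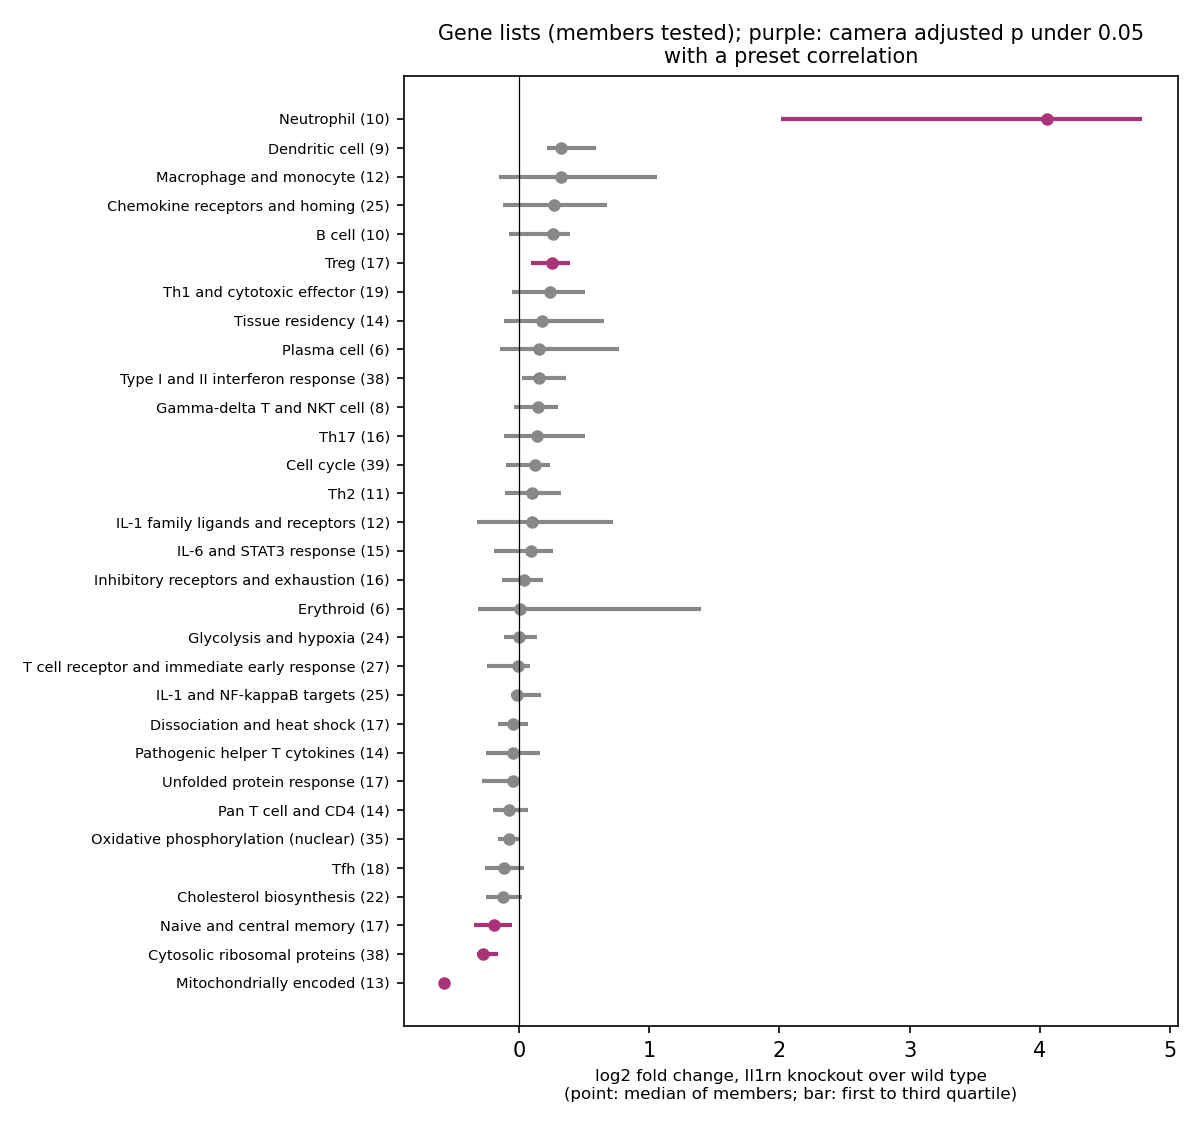
Median log2 fold change (knockout over wild type) of the tested members of each of the 31 gene lists, with bars from the lower to the upper quartile and the number of members in parentheses; purple marks camera adjusted p under 0.05 with the preset correlation. The neutrophil list stands at 4.06, and the other 4 lists that passed have medians between -0.575 and 0.254.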

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

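Camera without the neutrophil list, the mitochondrial share as a covariate and the term for the side of the library split were chosen after seeing the data. The 7 changed genes were 7 with RLE or upper-quartile scaling, a stricter filter, a robust edgeR fit or no receptor segments, and 6 when mitochondrial and sex-linked genes were left out. All 7 were among 58 genes with no filter (24 higher, 34 lower; 20255 tested), 11 with the replicate block (5 higher, 6 lower), 25 with DESeq2 (11 and 14), 11 with limma voom and quality weights (4 and 7), 14 with the mitochondrial share as a covariate (7 and 7) and 12 with the side term (6 and 6). Leaving out 1 library gave 3 to 10 genes. The replicate numbers were not taken to pair the samples, since the labels do not say that they do. Deviations of same-numbered libraries correlated at 0.108, 0.053 and 0.116, and each library correlated best with its own number. That is a hint of pairing from the data and not from the design. By edgeR, 1228 genes had an unadjusted p under 0.05 with the block, against 545 without it. The 5 lists that passed were 5 with RLE, 6 with upper-quartile scaling, no filter or a stricter filter, 7 with the replicate block, 4 without the neutrophil list, 6 with either added term, 4 to 8 without 1 library, 0 with an estimated correlation and 1 with fry. The block ended no call and added the interferon (median 0.139, adjusted p = 0.0432) and oxidative phosphorylation lists (-0.091, 0.0432).

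No changed gene reversed its direction in these fits, and of the 5 lists that passed the ribosomal list alone did; the cause was not tested. Bcl6 had a log2 fold change of -0.002 with RLE and -0.003 with DESeq2, and the Th17 list a median of -0.024 with no filter. With the mitochondrial share as a covariate, medians were 0.117 for ribosomal proteins, 0.171 for oxidative phosphorylation, 0.12 for pan T cell, 0.07 for glycolysis, 0.056 for inhibitory receptor, 0.046 for heat shock and 0.031 for pathogenic cytokine genes; the mitochondrial list itself stood at -0.087, as the covariate is its own share. With the side term, they were 0.034 for glycolysis, 0.009 for oxidative phosphorylation and 0.004 for pan T cell genes. Of 70 named genes that did not pass, 49 moved by over 1.5 times without 1 library. In these fits log2 fold changes ran from -0.069 to 0.559 for Tcrg-C2, -0.069 to 0.327 for Il4, -0.214 to 0.156 for Bcl6, -0.711 to 0.411 for Il17a, -0.601 to 0.196 for Il1r2 and -0.051 to 2.331 for Csf3r. List medians ran from -0.273 to 0.288 for Th17, -0.212 to 0.047 for pathogenic cytokines, 0.098 to 0.309 for tissue residency, -0.015 to 0.342 for gamma-delta and natural killer T cells, -0.181 to 0.93 for plasma cells, -0.041 to 0.071 for inhibitory receptors, -0.081 to 0.084 for immediate early genes, -0.196 to 0.059 for heat shock, -0.026 to 0.071 for NF-kappaB targets, 0.041 to 0.171 for interleukin-6 and STAT3, -0.306 to 0.507 for erythroid genes, -0.047 to 0.036 for glycolysis, -0.292 to 0.011 for oxidative phosphorylation and -0.32 to 0.017 for pan T cell genes, where a reversal was read from the direction of the test. Medians that kept it ran from 0.051 to 0.259 for Th1, -0.063 to 0.179 for Th2, -0.186 to -0.061 for follicular helper, 0.047 to 0.142 for interleukin-1 family, 0.055 to 0.216 for interferon, 0.019 to 0.166 for cell cycle, 0.145 to 0.228 for chemokine receptor, -0.124 to -0.069 for cholesterol, -0.272 to -0.028 for unfolded protein, 0.002 to 0.547 for B cell, 0.223 to 0.669 for macrophage and 0.204 to 0.526 for dendritic cell genes. Il1rn averaged 0.316 and 0.103 CPM in wild type and knockout with TMM-scaled totals. At totals of 14102183 to 17677217 counts, Il1rn and Csf2 were too sparse to compare.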

Other observations

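The tests of loci near Il1rn and near each other (except that of the H2-Q sum), of the neutrophil list and of the mitochondrial and ribosomal shares were chosen after the result was seen, as were the genes singled out here. In the genotype split 7 genes had at least 10 counts in every library of a group and none in the other, against 2 to 5 in the other splits of the libraries. Trav11d, a T cell receptor alpha V segment on chromosome 14, had 0 counts in every wild-type library and 3.98, 3.97 and 0.806 CPM in Il1rnKO 1, 2 and 3, while its near-copy Trav11 had 2.25, 4.02 and 5.96 CPM in WT 1, 2 and 3 and 0, 0 and 3.53 CPM in Il1rnKO 1, 2 and 3. Reads of such copies may have been divided by estimate, and neither segment passed edgeR with the main settings (adjusted p = 0.305 and 0.988), while Trav11d passed with no filter (7.65e-05) and with DESeq2 (7.7e-05), and Trav11 without Il1rnKO 3 (0.0408). The TMM-scaled level of Grip2, a scaffold gene of glutamate receptors, was 1264.5, 11984 and 22968 CPM in WT 1, 2 and 3 and 2846.3, 6334.8 and 1476.2 CPM in Il1rnKO 1, 2 and 3. Grip2 passed edgeR with no filter alone (log2 fold change -1.77, adjusted p = 0.0119). Its level varied widely within wild type, and whether the reads assigned to it come from this gene was not tested.

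The number of changed genes and of changed lists was set against the other splits of the 6 libraries into 3 and 3. For genes, 2 of the 10 splits gave at least 7: the genotype split itself and that of WT 1, Il1rnKO 1 and Il1rnKO 2, with 887. All remaining splits called 0 genes. For lists, 4 of the 10, the genotype split among them, gave at least 5, the highest other being 8. With 10 splits no share under 0.05 can be reached.

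Several of the changed genes lay near Il1rn or near one another: Sfmbt2 and Gm13443 were 14 Mb before and 11 Mb after Il1rn on chromosome 2, 2 of the 7 calls in a window of 20 Mb to either side that held 2.14% of the tested genes with a position. Division of reads between H2-Q copies is argued against as the whole cause, since the summed H2-Q CPM was itself higher by 0.661 on the log2 scale, with no overlap. DNA around the targeted locus that differs between the mice cannot be told apart from chance by its test, because 3 of 285 genes near Il1rn and 99 of 13053 elsewhere had an unadjusted p under 0.01 (odds ratio 1.39, 95% interval 0.281 to 4.23, Fisher's exact p = 0.482). Differing genetic background elsewhere stays open as a hypothesis. Among the 100 genes with the smallest p over 20 Mb from Il1rn, 15 pairs lay within 500 kb with the same sign. In 10000 random draws the median was 2 and the highest 12 (permutation p = 1e-04, the smallest they can give). The other splits gave 2 to 11, and 9 of the 15 pairs joined genes of different name stems. The pairs do not stand for separate loci: many joined H2-Q5, H2-Q6, H2-Q7, Gm16181 and Stk19 on chromosome 17. Others joined Srp54a, Srp54b and Fam177a, the overlapping Glo1 and Dnah8, S100a8 and S100a9 of the neutrophil list, or Il1rl1 and Il18rap. The rest joined Oas2 and Oas1b, and Ctns and Itgae, the last of which is in the regulatory T cell and tissue residency lists. The draws took genes singly, so neither the count nor the p-value measures how many loci differ. An effect of the missing antagonist on these genes was not separated from their position.

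Neutrophil transcripts marked the knockout libraries: of 15 listed members with at least 10 counts, 10 had every knockout library above every wild-type library. The chance share of 5% holds for a single member, and members of a list may vary together (estimated correlation 0.193). So the 10 members are not independent of one another. Ngp, Mmp8 and Wfdc21 had 0 counts in every wild-type library and reached 10 counts through the knockout libraries alone. Of the 15, 1 is also in another list, and 2 averaged at least 1 CPM in wild type. Of the B cell, macrophage, dendritic cell and erythroid lists, 2 had a summed CPM higher in every knockout library. A sort that was less pure for every other cell type alike cannot be told apart by these sums. Single genes made up most of some of them, so they are weak measures of purity. In wild type Tfrc averaged 114 CPM (TMM-scaled), beside an erythroid sum of 99.56 to 147.4 CPM. Ighm averaged 115 CPM (TMM-scaled), beside 121 to 165.8 CPM of B cell genes. Transcripts already present in wild type would also hide a small added share. A small amount of neutrophil RNA or cells in the knockout sorts stays open as a hypothesis too. Levels reached 34.2 CPM for S100a9 and 0.353 CPM for Retnlg. A sort of live CD4+ T cells is meant to exclude neutrophils, but its purity was not analysed here. Whether these transcripts follow the genotype through more neutrophils in the spleen, or through expression in the T cells, was not tested.

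The mitochondrial and ribosomal shares, and the 887-gene split of the libraries, may share a technical origin. The high knockout library had 8.339% mitochondrial counts, within the wild-type range of 5.676 to 8.917%, as a gradient running across both groups predicts. That prediction was written after these shares were seen, so its outcome was fixed and it adds no support. In the split of WT 1, Il1rnKO 1 and Il1rnKO 2 from the rest, 173 genes were higher and 714 lower, with medians of -1.107 for mitochondrial and -0.782 for ribosomal protein genes. Across genes, which are not independent replicates, its fold change rose with exonic length (Spearman's rho 0.307; 0.105 for the genotype), as a difference in coverage of long and short transcripts predicts, while GC content bias cannot be told apart (rho 0.187, between the bounds set beforehand). An effect of genotype on these transcripts stays open beside this structure, since 2 of the 3 knockout libraries lie on its low side.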
